A study of Mus musculus with 21 samples.

How the data were processed

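RNA was measured in LT-HSC, MPP2 and MPP3 sorted from the bone marrow of Phf6 WT and KO mice of strain C57BL/6 at 12 weeks of age, per the labels. The sort used a lineage cocktail, Sca-1, cKit, CD150 and CD48, with no stain for Flt3, per the labels' protocols. Each library came from 100 to 200 sorted cells and was made with the Nextera XT kit, per the labels' protocols. The deposited values are raw read counts per gene, aligned with STAR to mm10 per the submitters' processing notes. The counting program, the annotation release, the STAR version and the KO allele are not given in the sources used here. The table holds 54446 gene IDs and 21 columns of whole numbers, with 0 columns of other samples. Of the IDs, 54409 matched GENCODE M21 without the version and 37 did not, and 101 symbols were shared by more than 1 ID. Coordinates are from that annotation, in mm10. How reads shared between near-identical genes were counted is unknown, so values of histone, ribosomal protein and immunoglobulin genes are uncertain one by one.

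The groups were taken from the labels: 2 WT and 3 KO LT-HSC, 4 WT and 4 KO MPP2, and 4 WT and 4 KO MPP3 libraries. Before testing, 0 pairs of libraries had identical counts. The 6 libraries numbered 2 had at most 131 Xist and at least 2071 Ddx3y counts, and the 15 others at least 1743 Xist and at most 3 Ddx3y counts, so mouse 2 of each genotype was male by these genes. A share of 0 counts was set against a floor of 3 counts, 0.0985 to 0.194 CPM per library. Counting intervals are exact at 95%, and both floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

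Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood, robust, TMM factors) in 1 fit of all 21 libraries. Genes were kept by filterByExpr over the 6 groups with a minimum count of 10, which left 21100. For the mouse as the unit, the counts of MPP2 and MPP3 were added per mouse, and 17912 genes were tested over the 8 sums. KO was compared with WT in each population and in the sums, the WT populations with each other, and the KO effects between populations. P values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Levels of Phf6 and Sva were also compared by exact two-sided permutation tests, which took the libraries as unpaired. Exchanges within 4 pairs alone could not give a p under 0.05. Sva was chosen after its values were seen, and with no overlap between its groups its p could only be the smallest possible.

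The 29 gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 4 comparisons of KO with WT together, and apart from these over the WT comparisons. Camera with an estimated correlation and fry were run beside it. Single members were also adjusted over their list alone, within 1 comparison. These calls were not adjusted over the 29 lists or over the comparisons, so some of them would be expected by chance. The lists were stem cell identity, megakaryocyte-erythroid, granulocyte-monocyte, lymphoid priming, cell cycle, quiescence, TNF NF-kB, interferon, JAK-STAT, p53, immediate early and heat shock, ribosome biogenesis, oxidative phosphorylation, glycolysis, Hox and Meis, Notch, NuRD and PAF1, TGF-beta and adhesion, and apoptosis. Markers of B cells, T and NK cells, neutrophils, erythroid cells, macrophages, mast cells and basophils, and stroma made up further lists, as did ribosomal proteins, mitochondrially encoded genes and replication-dependent histones. Lists needed at least 5 tested members. The groups, tests, lists and alternatives were fixed before the data were examined, except where stated.

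Genes were named by a rule fixed at the same time. Phf6 was always named. In each comparison, the rule took the 8 higher and 8 lower genes with the largest fold change among those past the threshold, with a mean of at least 10 CPM in the higher group and no overlap between groups. Where fewer than 5 passed, it added the 5 genes of smallest p among the rest with at least 10 CPM. It also took up to 3 members of smallest p from each list, and passed over predicted gene models. Not all genes it took are printed, and some genes, 1 of those called in MPP2 among them, are not reported here. Sva, under 10 CPM, and Tespa1 and 2610307P16Rik fall outside it and were named after their values were seen.

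The numbers of the libraries were taken to mark mice, since the sample titles of libraries with the same genotype and number carry consecutive numbers, KO LT-HSC 3 excepted, and the series' design text speaks of pairs of WT and KO mice. As a check of the pairs, deviations from group means were correlated between KO and WT libraries of the same number. These are different mice, so this cannot show that a number marks 1 mouse. The correlations were 0.249, 0.237, 0.207 and 0.282 in MPP2, 0.116, 0.141, 0.136 and 0.0807 in MPP3 and 0.0417 and 0.0390 in LT-HSC. Libraries with other numbers had means of -0.0811, -0.0400 and -0.0202, which centring on group means itself pulls below 0. These means also pool numbers 1 and 2 with 3 and 4, which stood apart, and both mice numbered 2 were male. Either could raise same-number values without pairs. Each KO MPP2 library correlated best with the WT MPP2 library of its own number. In MPP3 this held except for number 4. Within WT, MPP2 and MPP3 libraries of the same number correlated at 0.105, 0.136, 0.100 and 0.0655. Within KO they did so at 0.405, 0.0537, 0.184 and 0.185. LT-HSC libraries 1 and 2 correlated with those of their number at -0.00764 to 0.0841 in WT and -0.0140 to 0.138 in KO, so the check is weak there. KO LT-HSC 3 correlated more closely with KO mouse 4 (0.148 in MPP2 and 0.120 in MPP3) than with KO mouse 3 (0.0515 and 0.0121). Its title number also directly follows those of KO mouse 4, as the LT-HSC libraries of KO mice 1 and 2 follow theirs, and not those of KO mouse 3. Both point to mouse 4, and the name KO LT-HSC 3 is kept as labelled. Libraries numbered 1 and 2 also stood apart from those numbered 3 and 4, and values within each are given as within batches. No label names a batch, and the word stands here only for these sets of numbers.

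Alternatives were size factors of DESeq2, no filter, a stricter filter at 20 counts, the DESeq2 1.42.0 test, limma voom with quality weights, a fit of only the groups compared, the replicate number as a block, and each library left out in turn. For the sums, mean log2 CPM tested with limma trend was added. After the data were seen, fits without KO MPP2 1, KO MPP3 1 and KO MPP3 2, without immunoglobulin genes, and with a term for numbers 1 and 2 against 3 and 4 were added. So were list tests with the block and an estimated correlation or fry, WT list tests without each library, and WT comparisons with the libraries numbered 1 and 2 or 3 and 4 alone.

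The steps were tested on simulated counts with genes changed by known folds. For KO against WT, edgeR recovered 0%, 75% and 82.9% of genes of at least 10 CPM changed 2-fold, 4-fold and 8-fold in LT-HSC. The shares were 10.3%, 84.6% and 92% in MPP2, 16.1%, 75% and 100% in MPP3, and 37.1%, 88.6% and 100% in the sums. False calls were 5 of 60, 2 of 62, 1 of 69 and 2 of 97. In the simulation of MPP2, DESeq2 made 48 false calls of 122. Camera recovered the 1 list moved 1.5-fold in all 4 simulations and called 0 others. The simulated genes were drawn independently of each other, without batches or pairs of mice. So the simulations cannot show how the preset correlation fares where genes move together, nor the false calls that a batch would give.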

Results

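RNA-seq counts were collected from 21 libraries of haematopoietic cells sorted from mouse bone marrow, wild type (WT) or knockout (KO) for Phf6, a nuclear protein with plant homeodomain fingers that is mutated in human T-cell leukaemia. LT-HSC are long-term haematopoietic stem cells, and MPP2 and MPP3 are multipotent progenitors downstream of them. The groups held 2 WT and 3 KO LT-HSC libraries, 4 WT and 4 KO MPP2 libraries, and 4 WT and 4 KO MPP3 libraries. Libraries are named by group and number, so that KO MPP2 1 is the MPP2 library of KO mouse 1, except that the mouse of KO LT-HSC 3 is uncertain. Total counts ran from 18892723 (KO MPP3 2) to 31611366 (KO MPP2 1), with a median of 26158938. Genes with at least 1 count ran from 20260 to 28501 per library. The questions were which genes changed in each population when Phf6 was lost, whether the change differed between populations, and how the populations differed in WT mice. Levels are in CPM, counts scaled to library size with TMM factors, given as mean ± SD, and log2 fold changes are given ± SE. The SE was taken as the absolute log2 fold change over the square root of the edgeR F statistic. A count of 3 stood for 0.0985 to 0.194 CPM, depending on the library.

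Phf6 (ENSMUSG00000025626.16, chromosome X, 52912266 to 52956943 on the plus strand in mm10) was low in all 11 KO libraries, with 43 to 395 counts against 1545 to 5204 in the 10 WT libraries. The level in LT-HSC was 9.64 ± 3.73 CPM in KO (n = 3) and 150 ± 37.8 CPM in WT (n = 2). In MPP2 it was 11.8 ± 0.412 CPM in KO (n = 4) and 138 ± 61.7 CPM in WT (n = 4), and in MPP3 9.01 ± 4.91 CPM in KO (n = 4) and 131 ± 56.8 CPM in WT (n = 4). These means put KO at 0.0641, 0.0857 and 0.0688 of WT. The log2 fold changes were -3.96 ± 0.585 in LT-HSC, -3.54 ± 0.478 in MPP2 and -3.85 ± 0.485 in MPP3, with edgeR adjusted p values of 0.0371, 0.0104 and 0.00376. Exact two-sided permutation tests of the levels gave p = 0.1 in LT-HSC, and p = 0.0286 in both MPP2 and MPP3. Each is the smallest p that the number of libraries allows when they are taken as unpaired. With exchanges only within pairs no p under 0.05 could be reached. WT mouse 3 had the lowest WT levels, 61.2 CPM in MPP2 and 54.4 CPM in MPP3. The LT-HSC call was lost without any 1 of its 5 libraries (edgeR adjusted p from 0.107 to 0.514), that in MPP2 without KO MPP2 2 (0.0510) or KO MPP2 3 (0.0526), and that in MPP3 without KO MPP3 1 (0.0549). With the replicate number as a block, the edgeR adjusted p was 0.610 in LT-HSC and 0.0556 in MPP2. With only the groups compared in the fit it was 0.9997 in LT-HSC and 0.252 in MPP3, and with a term for numbers 1 and 2 against 3 and 4 it was 0.130 in LT-HSC. No WT LT-HSC library is numbered 3 or 4, so in LT-HSC the block and this term both fit KO LT-HSC 3 apart. Their LT-HSC values thus compare only the libraries numbered 1 and 2.

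**Figure D1:**
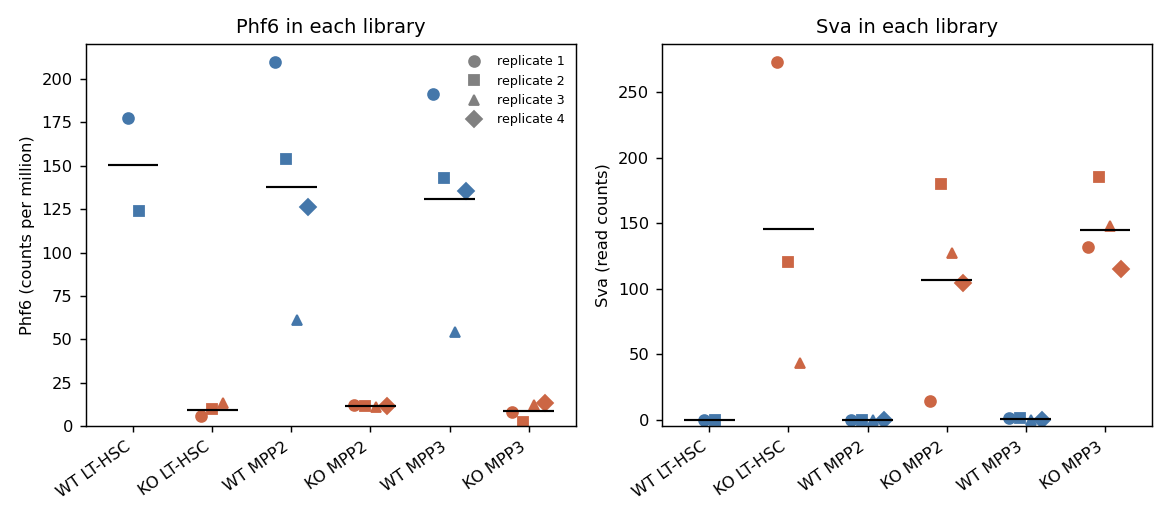
Phf6 in CPM and Sva in read counts, 1 point per library in the 6 groups. All 11 KO libraries lie below all 10 WT libraries for Phf6, and for Sva the KO libraries hold 14 to 273 counts against at most 1 in any WT library.

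In LT-HSC, the stem cells, granulocyte-monocyte transcripts lay lower in KO as a group, and respiratory, ribosome biogenesis and cell cycle transcripts slightly higher, by camera with its preset correlation. None of these list calls held with an estimated correlation (adjusted p = 0.944) or by fry, and that of cell cycle was lost without KO LT-HSC 2 (camera adjusted p = 0.730). KO LT-HSC 3 stood apart from the other LT-HSC libraries, with 20297 genes of at least 1 count against 23786 to 24827. Its voom quality weight was 0.359 against 0.744 to 2.225. Phf6 was the single gene of 21100 past the threshold. Sva had 43 to 273 counts in each of the 3 KO libraries and 0 in both WT libraries, at least 96.7-fold higher in KO against a floor of 3 counts over the group. It missed the threshold in edgeR (adjusted p = 0.358; exact unpaired permutation p = 0.1, the smallest possible), but passed in DESeq2 (adjusted p = 3.80e-05) and in limma voom (adjusted p = 0.00229). Under the other alternatives, all in edgeR, the adjusted p ran from 0.172 to 1. Of the 30 measured genes of the granulocyte-monocyte list, 25 had lower fitted levels in KO, with a median log2 fold change of -1.13, or -1.21 without 2 members at 3 counts or fewer in both groups. Plac8, a myeloid surface-associated protein, was at 50.1 ± 39.4 CPM in KO (n = 3) and 171 ± 65.0 CPM in WT (n = 2). Clec12a, a myeloid lectin receptor, had a log2 fold change of -5.75 ± 2.24. The list passed camera with its preset correlation (adjusted p = 5.69e-09; adjusted p = 0.944 with an estimated correlation). Its members held 0 calls over all genes and 1 adjusted over the list alone, Cebpa, a myeloid transcription factor (0.0590 CPM in KO, 0.626 in WT). Neutrophil transcripts were present in WT LT-HSC 2, where that list took 0.535% of counts against 0.00177% in WT LT-HSC 1 and at most 0.00688% in KO LT-HSC. Of the 6820 WT counts of Lcn2, a neutrophil granule protein, 6784 came from WT LT-HSC 2. The neutrophil list was lower in KO for 14 of 15 members (camera adjusted p = 3.56e-05; adjusted p = 0.944 with an estimated correlation). That call was lost without WT LT-HSC 2 (camera adjusted p = 0.866), whereas the granulocyte-monocyte call held without each of the 5 libraries.

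Genes of energy production and growth lay slightly higher in KO LT-HSC as groups with the preset correlation alone. In the oxidative phosphorylation list 43 of 45 members were higher (median log2 fold change 0.22, camera adjusted p = 9.03e-07). Cox7b, a cytochrome c oxidase subunit, was at 359 ± 30.5 CPM in KO and 258.5 ± 0.594 CPM in WT, and Ndufb5, of complex I, at a log2 fold change of 0.33. Ribosome biogenesis was higher for 34 of 40 members (median 0.24, camera adjusted p = 0.000178), among them Nip7 and Nop58 at 0.55 and 0.37. Cell cycle genes were higher for 36 of 40 (median 0.25, camera adjusted p = 0.000178), among them Nusap1 at 0.57. Interferon response genes were higher for 27 of 34 (median 0.29, camera adjusted p = 0.000343), with the antiviral regulator Irf7 at 0.77 and Ifit1 at 1.38. Ribosomal proteins were higher for 72 of 87 (median 0.10, camera adjusted p = 0.00240), with Rps27l at 0.51. Replication-dependent histones were lower for 41 of 58 (median -0.31, camera adjusted p = 0.0345), with Hist2h4 at -1.42. For each of these 6 lists the adjusted p was 0.944 with an estimated correlation, and 0 members passed, over all genes or adjusted over the list alone. Among single genes with the smallest p, none of which passed (edgeR adjusted p from 0.871 to 1), the centrosomal gene Cep72 was at 11.4 ± 4.68 CPM in KO and 2.44 ± 1.36 CPM in WT. Sox6, a transcription factor, was at 13.4 ± 6.75 and 60.9 ± 6.60, Dpp4, a peptidase, at 13 ± 9.12 and 45.2 ± 0.716, and Cd37, a tetraspanin, at 35.3 ± 12.3 and 73.8 ± 2.43. Ifitm6 had 764 counts in WT, 751 of them in 1 library, and 0 in KO. Flt3 was at 21.4 ± 16.3 CPM in KO and 74.8 ± 18.4 in WT, and Lsp1, also of the lymphoid priming list, had a log2 fold change of -0.80. The platelet chemokine Pf4 was at 465.5 ± 204 and 107.5 ± 48.7 CPM. No WT LT-HSC library shares the number of KO LT-HSC 3, so the block fits it apart. The block values that follow thus compare only the libraries numbered 1 and 2. With the block, the lymphoid priming list (13 of 20 lower; camera adjusted p = 0.0513 without the block) reached 0.00419 and the megakaryocyte-erythroid list (23 of 29 higher; 0.0911) 0.00312. The TNF NF-kB and Notch lists reached camera adjusted p values of 0.0209 and 0.0302 with the block, while the calls of histones (0.0730) and ribosomal proteins (0.892, turned) were lost. None of the 4 gained calls held with the block and an estimated correlation (adjusted p from 0.530 to 0.710) or with the block by fry. Phf6 was not called with the block, and Tespa1, a thymocyte gene, was (log2 fold change -1.74, edgeR adjusted p = 0.0102). Single omissions ended the cell cycle call (camera adjusted p = 0.730 without KO LT-HSC 2), the interferon call (0.390 without KO LT-HSC 1) and the ribosomal protein call (0.0817 without WT LT-HSC 1 and 0.991, turned, without KO LT-HSC 3). The histone call ended too (camera adjusted p = 0.743 without WT LT-HSC 1, 0.339 without KO LT-HSC 1 and 0.0734 without KO LT-HSC 3). Of the batches set by the numbers of the mice, 1 and 2 against 3 and 4, the second held no WT LT-HSC library. Within numbers 1 and 2 the list medians were -0.93 for granulocyte-monocyte, 0.16 for oxidative phosphorylation, 0.24 for ribosome biogenesis, 0.43 for cell cycle, 0.44 for interferon, -0.01 for ribosomal proteins and -0.15 for histones, and Phf6 was at -4.25.

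MPP2, progenitors held to be biased to megakaryocytes and erythroid cells, gained Sva in KO, and genes of the stem cell and lymphoid lists lay lower by camera with its preset correlation. No list call in MPP2 held with an estimated correlation (adjusted p = 0.944) or by fry, and that of lymphoid priming was lost without any 1 of 4 libraries. Sva (ENSMUSG00000023289.11, chromosome 6, 42038394 to 42042851 on the plus strand in mm10) encodes seminal vesicle antigen, a secretory protein. Its level was 4.10 ± 2.62 CPM in KO MPP2 (n = 4), from 425 counts, against 0 counts in the 4 WT libraries, at least 152-fold higher (edgeR adjusted p = 0.0119; exact unpaired permutation p = 0.0286, the smallest possible). Phf6 and Sva were among the 3 genes past the threshold. The Sva call in MPP2 was lost without WT MPP2 1 (edgeR adjusted p = 0.0534), WT MPP2 2 (0.0536), WT MPP2 4 (0.0518), KO MPP2 2 (0.0510) or KO MPP2 3 (0.0526), and with only the groups compared in the fit (0.998). With the block the edgeR adjusted p was 0.0772 for Sva, and 9 genes passed, 8 immunoglobulin genes and 2610307P16Rik, 0 of these 3 among them. Within numbers 1 and 2, and within 3 and 4, Phf6 was at -3.92 and -3.01. Sva was at 0 counts in WT in both batches.

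Of 36 stem cell identity genes, 27 were lower in KO MPP2 (median log2 fold change -0.34, camera adjusted p = 5.34e-05; adjusted p = 0.944 with an estimated correlation), with 0 past the threshold over all genes and 1 adjusted over the list alone. Mecom, a transcription factor that stem cells need, was at 13.5 ± 6.84 CPM in KO and 35.8 ± 20.2 in WT, and Ifitm1 at a log2 fold change of -0.93. The Hox and Meis list was lower for 14 of 20 (median -0.34, camera adjusted p = 0.00732), with Hoxa9 at 42.8 ± 19.3 CPM in KO and 85.6 ± 34.7 in WT and Hoxa10 at -0.70. Lymphoid priming genes were lower for 15 of 20 (median -1.11, camera adjusted p = 0.0105), with Satb1, a chromatin organiser, at -1.43. The same list stood higher in MPP2 libraries numbered 1 and 2 than in those numbered 3 and 4, by a median of 3.50, with Flt3 at 137 to 591 and 4.81 to 40.9 CPM in them. Ribosome biogenesis was higher for 34 of 40 (median 0.20, camera adjusted p = 0.000802), with Nat10, Tcof1 and Heatr1 at 0.80, 0.57 and 0.55. Ribosomal proteins lay lower for 64 of 87 (median -0.08, camera adjusted p = 0.0251), with Rpl22l1 at -0.39. For these 4 lists the adjusted p was 0.944 with an estimated correlation, and 0 members passed. Stromal and endothelial markers were lower for 9 of 13 (camera adjusted p = 0.0103; adjusted p = 0.944 with an estimated correlation), 1 of them, Emcn, adjusted over the list alone. Emcn, endomucin, which stem cells also express, was at 3.69 ± 2.43 CPM in KO and 22.7 ± 13.7 in WT (edgeR adjusted p = 0.382). Neutrophil markers were higher for 14 of 15 (camera adjusted p = 0.04996; adjusted p = 0.944 with an estimated correlation). They took 0.798% of counts in KO MPP2 1 against at most 0.00491% in the other KO libraries and 0.0354% in WT MPP2 2. Without the 3 libraries rich in immunoglobulin or rRNA reads, an omission chosen after the data were seen, the ribosomal protein and neutrophil calls were lost (camera adjusted p = 0.508 and 0.504, the latter turned). None of the next genes passed (edgeR adjusted p from 0.382 to 0.565). Ganab, a glucosidase of the endoplasmic reticulum, was at 109 ± 13.2 CPM in KO and 63.3 ± 12.4 in WT, and Hdlbp, an RNA-binding protein, at 128 ± 28.7 and 73.75 ± 10.9. Krt18, a keratin, was at 38.9 ± 5.56 and 63.1 ± 3.98, and Zfp951, a zinc finger gene, at 8.67 ± 2.98 and 23.5 ± 6.94. Gata3, a T-lineage factor, was the 1 member of the Notch list called adjusted over the list alone, at -1.37, with no adjustment over the lists. The lymphoid priming call was lost without WT MPP2 1 (camera adjusted p = 0.381), WT MPP2 2 (0.645), KO MPP2 3 (0.121) or KO MPP2 4 (0.389). The ribosome biogenesis call was lost without WT MPP2 1 (0.0875), WT MPP2 2 (0.0712) or KO MPP2 4 (0.365). The ribosomal protein call was lost without WT MPP2 4 (0.665, turned) or KO MPP2 1 (camera adjusted p = 0.748), and the stromal call without KO MPP2 2 (0.0915). The neutrophil call was lost without WT MPP2 1 (camera adjusted p = 0.120), WT MPP2 3 (0.1735), WT MPP2 4 (0.132) or KO MPP2 1 (0.455, turned). Within numbers 1 and 2, and within 3 and 4, medians were -0.31 and -0.27 for stem cell identity, -0.65 and -0.12 for Hox and Meis, -1.16 and -0.46 for lymphoid priming, 0.16 and 0.26 for ribosome biogenesis, -0.00 and -0.13 for ribosomal proteins, and -0.57 and -1.83 for stromal markers.

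**Figure D2:**
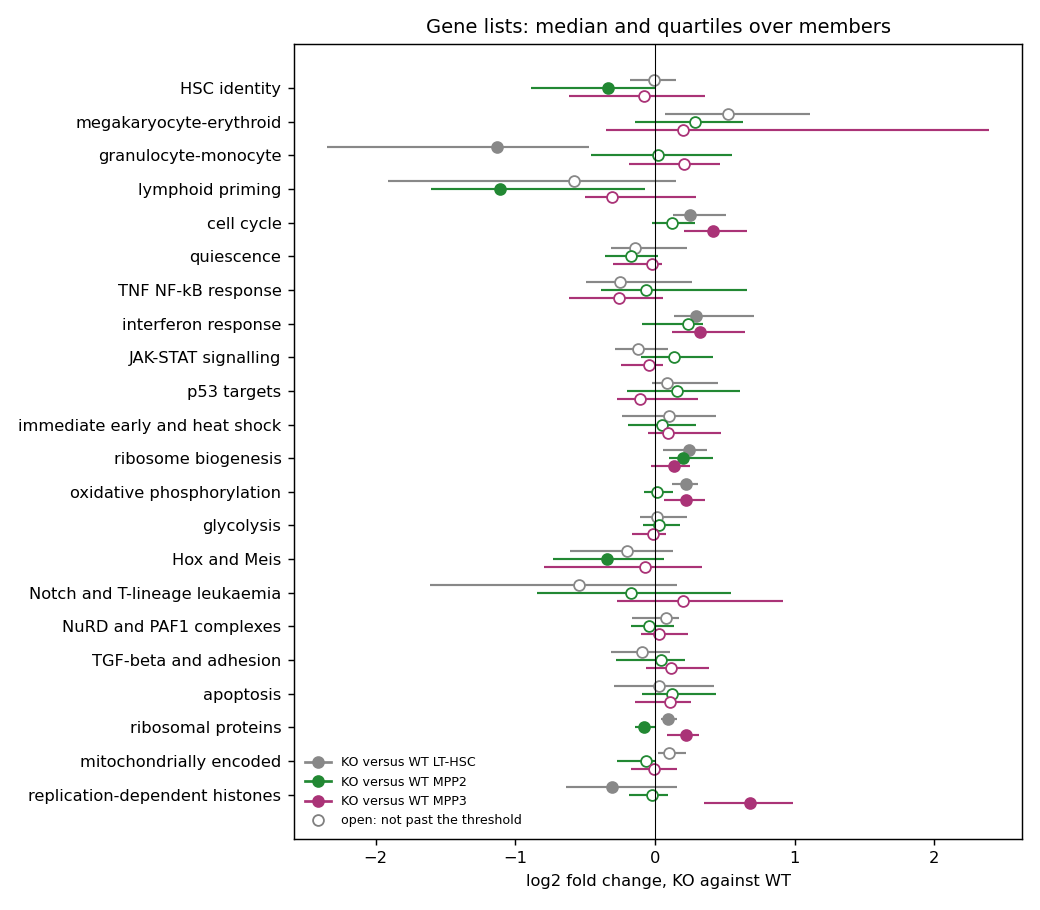
Gene lists in KO against WT LT-HSC, MPP2 and MPP3, with the log2 fold change on the x axis, dots for the median over members and bars for the quartiles; filled dots have a camera adjusted p under 0.05 with the preset correlation, and 0 lists did with an estimated one. In MPP3 the cell cycle and histone lists lie to the right at 0.41 and 0.68, and in LT-HSC the granulocyte-monocyte list lies to the left at -1.13.

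In MPP3, progenitors held to be biased to granulocytes and monocytes, Phf6 and Sva were the 2 genes past the threshold. The sort had no stain for Flt3 and so did not remove Flt3-expressing progenitors, and WT MPP3 had Flt3 at 923 to 1262 CPM and Dntt, the polymerase of antigen receptor joining, at 885 to 1434. Genes of proliferation, protein synthesis, respiration and the interferon response lay higher in KO as groups by camera with its preset correlation. None of these list calls held with an estimated correlation (adjusted p = 0.944) or by fry. Sva was at 6.37 ± 2.85 CPM in KO MPP3 (n = 4) and 0.0189 ± 0.0220 CPM in WT (n = 4), from 580 and 2 counts, a ratio of 324.5 (95% counting interval 89.4 to 2686; edgeR adjusted p = 0.0208; exact unpaired permutation p = 0.0286, the smallest possible). Its call was lost with the block (0.104) and without any 1 library (edgeR adjusted p from 0.0516 to 0.138) except KO MPP3 4 (0.0410). Within numbers 1 and 2, and within 3 and 4, the log2 fold change of Phf6 was -4.97 and -2.90. With the block 8 genes passed, Phf6 (edgeR adjusted p = 0.0331) and 7 immunoglobulin genes, and both Phf6 and Sva missed the threshold without the 3 libraries rich in immunoglobulin or rRNA reads (0.172 for each). Replication-dependent histones were higher for 51 of 58 (median log2 fold change 0.68, camera adjusted p = 5.54e-11), with the linker histone Hist1h1b at 35.6 ± 28.8 CPM in KO and 15.6 ± 2.93 in WT. The cell cycle list was higher for 36 of 40 (median 0.41, camera adjusted p = 6.94e-11), among them the mitotic genes Birc5, Bub1b and Nusap1 at 0.75, 0.80 and 0.64. Ribosomal proteins were higher for 81 of 87 (median 0.22, camera adjusted p = 4.31e-11). Ribosome biogenesis was higher for 26 of 40 (median 0.14, camera adjusted p = 0.0486), with Polr1a, of RNA polymerase I, at 0.66. Interferon response genes were higher for 28 of 34 (median 0.32, camera adjusted p = 9.20e-07), with Usp18 at 75.2 ± 36.8 and 34.2 ± 6.48 CPM, Oas2 at 1.2 and Bst2 at 0.50. For these 5 lists the adjusted p was 0.944 with an estimated correlation, and 0 members passed. Of the oxidative phosphorylation list 39 of 45 were higher (median 0.22, camera adjusted p = 3.06e-08; adjusted p = 0.944 with an estimated correlation), with 0 calls over all genes and 4 adjusted over the list alone. Cox7a2, a cytochrome c oxidase subunit, was at 353.5 ± 32 CPM in KO and 238 ± 24.4 in WT, Uqcrq, of complex III, at 217 ± 40.9 and 142 ± 21.7, and Ndufb3 at a log2 fold change of 0.38. The histone call was lost without the 3 libraries rich in immunoglobulin or rRNA reads (camera adjusted p = 0.194). That of ribosome biogenesis was lost with other size factors (camera adjusted p = 0.0592) or without WT MPP3 1 (0.313), WT MPP3 2 (0.302), KO MPP3 3 (0.523) or KO MPP3 4 (0.845). Medians within numbers 1 and 2, and within 3 and 4, were 0.93 and 0.13 for histones, 0.14 and 0.58 for cell cycle, 0.28 and 0.16 for ribosomal proteins, -0.11 and 0.24 for ribosome biogenesis, 0.22 and 0.40 for interferon, and 0.00 and 0.38 for oxidative phosphorylation.

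Markers of other cells also differed in MPP3. B-cell markers were higher for 13 of 13 (camera adjusted p = 0.0288; adjusted p = 0.944 with an estimated correlation). Immunoglobulin genes took 25.8% of counts in KO MPP3 1, against at most 0.0772% in the other KO MPP3 libraries and 0.0865% in WT MPP3. The call was lost without KO MPP3 1 (camera adjusted p = 0.925, turned), without WT MPP3 4 (0.109) and without the 3 libraries rich in immunoglobulin or rRNA reads (0.854). Neutrophil markers were lower for 14 of 15 (camera adjusted p = 0.0440; adjusted p = 0.944 with an estimated correlation), with 0.207% of counts in WT MPP3 1 against at most 0.0112% elsewhere in MPP3. That call was lost without WT MPP3 1 (camera adjusted p = 0.971, turned), KO MPP3 1 (0.203), KO MPP3 3 (0.110) or KO MPP3 4 (0.180), with the block (0.0546), with other size factors (0.0527) and without the 3 libraries (0.0516). Mast cell and basophil markers were lower for 6 of 8 (camera adjusted p = 0.0486; adjusted p = 0.944 with an estimated correlation), and 100 of the 104 counts of Cd200r3 lay in 1 WT library. That call was lost with other size factors (camera adjusted p = 0.0542) and without WT MPP3 3 (0.146), WT MPP3 4 (0.149), KO MPP3 1 (0.0963), KO MPP3 3 (0.184) or KO MPP3 4 (0.190). Cd63, a tetraspanin of granules, was the 1 member of the granulocyte-monocyte list called adjusted over the list alone, at 110 ± 27.6 CPM in KO MPP3 and 188 ± 36.8 in WT. It and the other genes of smallest p did not pass (edgeR adjusted p = 0.880). Muc13, a mucin, was at 131 ± 24 and 209 ± 22.2 CPM, and Incenp, of the chromosomal passenger complex, at 73.7 ± 13.7 and 36.3 ± 10.4. Eya2, a transcriptional coactivator, was at 20.9 ± 8.17 and 45.9 ± 8.51, and Txnip, a thioredoxin inhibitor, at 307 ± 47.4 and 500.2 ± 69.9. Emcn was at 15.1 ± 3.38 and 36.7 ± 13.2 CPM, and Pecam1, an adhesion molecule, and the signal transducer Stat3 at log2 fold changes of -0.62 and -0.37.

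With MPP2 and MPP3 summed for each mouse (4 KO and 4 WT sums), Phf6 and Sva again were the 2 genes of 17912 past the threshold. As groups, stem cell identity and lymphoid transcripts lay lower in KO mice, and cell cycle and interferon transcripts higher, by camera with its preset correlation. None of these list calls held with an estimated correlation (adjusted p = 0.944) or by fry, and those of interferon and lymphoid priming were lost without 1 mouse each. Phf6 had a log2 fold change of -3.69 ± 0.368 (edgeR adjusted p = 0.0237). Sva had a ratio of 547 (95% counting interval 151 to 4524, from 1005 KO and 2 WT counts; edgeR adjusted p = 0.0152). Cell cycle genes were higher for 35 of 40 (median 0.27, camera adjusted p = 1.62e-07), with Ccne1, a cyclin of the G1 to S transition, at 25.4 ± 7.28 and 14.3 ± 2.95 CPM, Tpx2 at 0.48 and Aurka at 0.47. Interferon response genes were higher for 27 of 34 (median 0.26, camera adjusted p = 7.93e-06), with Mx1, an antiviral GTPase, at 12.2 ± 5.21 and 3.985 ± 1.54 CPM, Isg15 at 1.07 and Usp18 at 0.86. Ribosome biogenesis (35 of 40 higher, median 0.17, camera adjusted p = 0.000463), oxidative phosphorylation (39 of 45, median 0.12, 0.00265) and histones (46 of 58, median 0.25, 0.00637) lay higher too, with Nat10 at 0.59, Uqcrq at 0.35 and Hist1h3c at 0.84. Stem cell identity genes were lower for 25 of 35 (median -0.18, camera adjusted p = 0.00148), with Txnip and Pdzk1ip1 at -0.55 and -0.66. Lymphoid priming genes were lower for 13 of 20 (median -0.39, camera adjusted p = 0.000629), although their mean was 0.01. Dntt was at 462 ± 159 CPM in KO and 764 ± 126 in WT, Flt3 at 439 ± 107 and 665 ± 165, and Rag2, of the recombinase, at 16.2 ± 5.98 and 28.4 ± 6.75. For each of these 7 lists the adjusted p was 0.944 with an estimated correlation, and 0 members passed. Megakaryocyte-erythroid genes were higher for 20 of 28 (median 0.34, camera adjusted p = 0.0109), with 1, the membrane skeleton gene Ank1, adjusted over the list alone at 5.19 ± 2.57 and 1.05 ± 0.532 CPM. Stromal markers were lower for 5 of 9 (camera adjusted p = 0.0288), with 2 adjusted over the list alone, Emcn at -1.69 and Pecam1 at -0.53. For both lists the adjusted p was 0.944 with an estimated correlation, and 0 members passed over all genes. None of the next genes passed (edgeR adjusted p = 0.573 for Cars and 0.995 for the others). Cars, a transfer RNA synthetase, was at 43.0 ± 3.46 and 24 ± 2.54 CPM, and Hsph1, a heat shock protein, at 70.8 ± 9.81 and 39.9 ± 7.18. Serpinf1, a secreted serpin, was at 23.3 ± 2.67 and 73.7 ± 33.8, and App, the amyloid precursor, at 5.58 ± 0.945 and 11.3 ± 0.934. Zfp951, Cd63, Csf3r and Gata3 had log2 fold changes of -1.33, -0.60, -0.53 and -0.89. With the block, 0 genes passed, Phf6 at an edgeR adjusted p of 0.350 and Sva at 0.135. Limma voom also gave 0 calls (adjusted p = 0.122 for both), and Phf6 missed the threshold with a term for numbers 1 and 2 against 3 and 4 (edgeR adjusted p = 0.0666). The TNF NF-kB, T and NK cell, macrophage and ribosomal protein lists reached camera adjusted p values of 0.0488, 0.0497, 0.0498 and 0.0376 with the block. None of these 4 held with the block and an estimated correlation (adjusted p = 0.776, 0.538, 0.538 and 0.811) or with the block by fry. The Phf6 call was lost without any 1 sum (edgeR adjusted p from 0.0536 to 0.240) except WT 3 (0.00146). That of Sva was lost without KO 2 (edgeR adjusted p = 0.0839), KO 3 (0.0711), WT 1 (0.0536), WT 2 (0.101) or WT 4 (0.0800). Without the 3 libraries rich in immunoglobulin or rRNA reads, the calls of interferon (camera adjusted p = 0.391), histones (0.712), stromal markers (0.0892), Phf6 (edgeR adjusted p = 0.339) and Sva (0.244) were lost. Omitting 1 sum ended the calls of interferon (0.207 without KO 1), lymphoid priming (0.0738 without KO 4) and ribosome biogenesis (0.292 without KO 4). It ended those of oxidative phosphorylation (camera adjusted p = 0.216 without KO 3, 0.0562 without KO 4 and 0.197 without WT 2) and histones (0.387 without KO 2 and 0.0838 without WT 2). It also ended those of megakaryocyte-erythroid genes (0.333 without KO 3, 0.394 without KO 4, 0.0709 without WT 1 and 0.623 without WT 2) and stromal markers (0.135 without KO 2, 0.0738 without KO 4, 0.0779 without WT 2 and 0.119 without WT 4).

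Whether the KO effect differed between populations was tested gene by gene. In edgeR, 0 of 21100 genes passed for LT-HSC against MPP2, LT-HSC against MPP3 or MPP2 against MPP3, with 759, 521 and 943 genes at an unadjusted p under 0.05 where 1055 would be expected, and limma voom called 0 in each. DESeq2 called 25, 27 and 13. So the Sva difference was not shown to be larger in 1 population than in another.

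In WT mice, LT-HSC had higher levels of stem cell transcripts than MPP2, and the list call held with an estimated correlation. Cell cycle, respiratory and myeloid transcripts lay lower with the preset correlation alone (adjusted p = 0.101, 0.150 and 0.436 with an estimated one), the myeloid ones mostly against the MPP2 libraries numbered 1 and 2. Of 21100 genes, 56 were higher and 77 lower in LT-HSC (n = 2) than in MPP2 (n = 4). Of the 36 stem cell identity genes, 5 were called higher over all genes and 25 adjusted over the list alone (median log2 fold change 1.60, camera adjusted p = 1.14e-24; adjusted p = 0.00324 with an estimated correlation). Mllt3, a regulator of stem cell maintenance, was at 221 ± 38.8 CPM in LT-HSC and 35.3 ± 6.14 in MPP2 (edgeR adjusted p = 0.0102). Sult1a1, a sulfotransferase, was at 86.9 ± 2.44 and 0.741 ± 0.939 (edgeR adjusted p = 0.0328), and Txnip at 870 ± 69.5 and 397 ± 64.4 (0.0328). The kinase gene Plk2 (28.2 and 0.0806 CPM), the Wnt antagonist Sfrp1, Tm4sf1, Tinagl1, the cytokine gene Il4, the nuclear receptor Nr4a1 and Kazald1 were also higher, at log2 fold changes of 8.39, 6.89, 6.61, 4.40, 3.73, 3.52 and 3.42. Lower in LT-HSC were Cd48, whose protein was used for the sort (9.62 ± 5.72 and 402 ± 124 CPM, edgeR adjusted p = 0.00399) and Cst7, a protease inhibitor (1.51 ± 0.598 and 99.6 ± 31.2 CPM). So were Ifi209 (0 counts in LT-HSC, at least 280-fold higher in MPP2), and Btnl9, Rab44, Tent5a, Bex6 and Cep72 (-3.56, -3.52, -3.49, -3.37 and -2.77). The cell cycle list had 2 members called lower, Nusap1 (-2.03) and Birc5 (-1.92), and 31 adjusted over the list alone (median -1.24, camera adjusted p = 1.84e-30; adjusted p = 0.101 with an estimated correlation). The oxidative phosphorylation list had 6 and 20 such members (median -0.56, camera adjusted p = 5.40e-20; adjusted p = 0.150 with an estimated correlation). Among granulocyte-monocyte genes 2 were called lower, Nkg7 (-2.66) and Plac8 (-2.77), and 8 adjusted over the list alone (median -1.96, camera adjusted p = 1.33e-05; adjusted p = 0.436 with an estimated correlation). Lymphoid priming genes (median -2.38, camera adjusted p = 0.000492; adjusted p = 0.528 with an estimated correlation) had 0 calls of either kind, with Satb1 at -3.08. Both WT LT-HSC libraries are numbered 1 or 2. Against MPP2 libraries numbered 1 and 2 the medians were -3.29 for lymphoid priming and -2.29 for granulocyte-monocyte genes, and against those numbered 3 and 4 they were 0.02 and -0.40. Flt3 was at 61.8 and 87.8 CPM in WT LT-HSC, 301 and 591 in WT MPP2 1 and 2, and 40.9 and 6.96 in WT MPP2 3 and 4. Mpo, a myeloid peroxidase, was at 2319 and 1134 CPM in WT MPP2 1 and 2, and at 390 and 21.6 in WT MPP2 3 and 4. B-cell markers lay lower in LT-HSC too (median -6.915, camera adjusted p = 0.0429; adjusted p = 0.638 with an estimated correlation), with immunoglobulin genes at 4.08% and 3.515% of counts in WT MPP2 1 and 2 and at most 0.00561% in WT MPP2 3 and 4. That call was lost without WT LT-HSC 2 (camera adjusted p = 0.110), WT MPP2 1 (0.1535) or WT MPP2 2 (0.1465). Mast cell and basophil markers lay lower as well (median -2.89, camera adjusted p = 0.0488; adjusted p = 0.427 with an estimated correlation), with 2 of 8 adjusted over the list alone. Megakaryocyte-erythroid genes (median -0.87, camera adjusted p = 0.0832; adjusted p = 0.638 with an estimated correlation) had 0 calls over all genes and 1 adjusted over the list alone, with Plek at -1.64. Their median was 0.26 against MPP2 libraries numbered 1 and 2 and -1.55 against those numbered 3 and 4. The medians against these were 1.49 and 1.79 for stem cell identity, -1.25 and -1.18 for cell cycle and -0.40 and -0.81 for oxidative phosphorylation, and 35 and 362 genes passed. The count of 133 genes fell to 5 without WT LT-HSC 1, 0 without WT LT-HSC 2, 57 without WT MPP2 1, 68 without WT MPP2 3 and 47 without WT MPP2 4. Of the 22 called genes named here, 0 stayed called in all 6 omissions. With the mouse as a block 54 genes passed, 28 of them among the 133, and 9 of the 22 named ones stayed called. The 13 others were Plk2, Sfrp1, Sult1a1, Tm4sf1, Tinagl1, Nr4a1, Kazald1, Btnl9, Rab44, Bex6, Cep72, Mllt3 and Birc5.

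Against MPP3, WT LT-HSC were higher in stem cell identity and megakaryocyte-erythroid transcripts and lower in lymphoid and granulocyte-monocyte ones, with 152 genes higher and 80 lower (n = 2 and 4). With an estimated correlation the first 2 list calls held and the last 2 were lost (adjusted p = 0.130 and 0.224). Of the stem cell identity list 15 of 36 were called higher and 26 adjusted over the list alone (median 2.29, camera adjusted p = 9.85e-55; adjusted p = 2.07e-05 with an estimated correlation). The adhesion molecule Esam was at 152 ± 16.5 CPM in LT-HSC and 14.6 ± 7.05 in MPP3 (edgeR adjusted p = 0.000224), and Pdzk1ip1 at 378 ± 54.5 and 50.3 ± 17.5 (0.000502). Megakaryocyte-erythroid genes had 4 of 29 called higher and 19 adjusted over the list alone (median 2.49, camera adjusted p = 2.61e-15; adjusted p = 0.0402 with an estimated correlation), with Apoe at 808 ± 228 and 85.1 ± 33.8 CPM and Car2 at 1.30. Cavin2, a caveolar coat protein, had 3677 counts in LT-HSC and 2 in MPP3, a ratio of 3467 (95% counting interval 959 to 28643). The ratios of Efna1, Tm4sf1 and Rhoj were 1461 (404 to 12072), 1443 (258 to 57062) and 813 (224 to 6723). Clca3a1, the retinaldehyde dehydrogenase Aldh1a1 (108 ± 10.6 and 0.716 ± 0.931 CPM), Cpne8 and Runx1t1 were higher at 8.04, 7.24, 7.06 and 7.05. Lymphoid priming genes had 2 of 20 called lower and 5 adjusted over the list alone (median -4.37, camera adjusted p = 1.06e-16; adjusted p = 0.130 with an estimated correlation), with Satb1 at 9.13 ± 3.28 and 274 ± 69.1 CPM and Il12a at 51.1 ± 20.3 and 292 ± 43.0. In the granulocyte-monocyte list 4 of 30 were called lower and 1, Cd63 (498 ± 14 and 188 ± 36.8 CPM), higher, and 10 adjusted over the list alone (median -1.90, camera adjusted p = 4.81e-10; adjusted p = 0.224 with an estimated correlation). Plac8 was at -3.02 and Cebpa at -3.61, and the macrophage colony-stimulating factor receptor Csf1r was at 485 times the LT-HSC level in MPP3 (166 to 2352). Clec2i was at 1778 times the LT-HSC level (319 to 70240). Ptger2, Ifi209 and Cd300lb were at least 520-fold, 442-fold and 383-fold higher in MPP3. Drc7, Cst7 and Cd48 were at -6.28, -6.10 and -5.71. The cell cycle list had 0 calls (median -0.39, camera adjusted p = 5.61e-05; adjusted p = 0.557 with an estimated correlation), with Hells at -0.93 and Mcm6 at -0.85. Markers of other cells also differed. T and NK cell markers lay lower in LT-HSC (median -1.50, camera adjusted p = 0.00416; adjusted p = 0.312 with an estimated correlation). Erythroid markers lay higher (median 0.86, camera adjusted p = 0.000722; adjusted p = 0.190 with an estimated correlation). Against MPP3 libraries numbered 1 and 2, and against those numbered 3 and 4, medians were 2.04 and 2.84 for stem cell identity, 1.90 and 2.46 for megakaryocyte-erythroid, -4.86 and -3.88 for lymphoid priming, -1.02 and -2.29 for granulocyte-monocyte, and -0.26 and -0.39 for cell cycle genes. In these, 48 and 114 genes passed. The count of 232 genes fell to 51 without WT LT-HSC 1, 54 without WT LT-HSC 2, and 131, 147, 117 and 121 without WT MPP3 1, 2, 3 and 4. Of the 25 called genes named here, 8 stayed called in all 6 omissions, namely Cavin2, Tm4sf1, Rhoj, Clca3a1, Aldh1a1, Cd48, Esam and Pdzk1ip1. With the mouse as a block 14 of the 25 stayed called, 6 of these 8 among them. Efna1, Tm4sf1, Aldh1a1, Cpne8, Runx1t1, Cd300lb, Csf1r, Drc7, Car2, Cebpa and Satb1 no longer passed.

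Comparing the progenitors, WT MPP2 were higher than WT MPP3 in megakaryocyte-erythroid and cell cycle transcripts, with 207 genes higher and 46 lower (n = 4 and 4). With an estimated correlation the first of these list calls held and that of cell cycle was lost (adjusted p = 0.144). Of 29 megakaryocyte-erythroid genes 11 were called higher and 19 adjusted over the list alone (median 2.75, camera adjusted p = 4.64e-21; adjusted p = 0.0199 with an estimated correlation). Epor, the erythropoietin receptor, was at 35.7 ± 25.7 and 0.248 ± 0.469 CPM (edgeR adjusted p = 0.0448), and Apoe at 1478 ± 1122 and 85.1 ± 33.8 (0.00258). The lipid transporter Mfsd2b was at 188 ± 136.5 and 1.29 ± 1.36 CPM (edgeR adjusted p = 0.0142), and the water channel Aqp1 and tetraspanin Cd9 at log2 fold changes of 5.73 and 2.07. The transporter Slc38a5 had 3780 counts in MPP2 and 0 in MPP3, at least 1328-fold higher. Cavin2 had a ratio of 3529 (95% counting interval 976.5 to 29145). The erythroid genes Tspo2 and Rhd, and Ces2g and Nxpe2, were at 9.94, 8.0, 9.27 and 8.03. Of the cell cycle list 6 of 40 were called higher and 22 adjusted over the list alone (median 0.89, camera adjusted p = 1.66e-21; adjusted p = 0.144 with an estimated correlation), with Nusap1, Birc5 and Ube2c at 1.58, 1.64 and 2.45. Oxidative phosphorylation had 13 of 45 called higher and 22 adjusted over the list alone (median 0.51, camera adjusted p = 2.12e-19; adjusted p = 0.150 with an estimated correlation). Stem cell identity had 5 of 36 called higher and 10 adjusted over the list alone (median 0.39, camera adjusted p = 2.58e-06; adjusted p = 0.144 with an estimated correlation). The latter included Tek, the angiopoietin receptor (23.5 ± 6.64 and 4.46 ± 0.925 CPM), Nupr1 (5.07) and Slamf1, the gene of the sort antigen CD150 (49.0 ± 33.5 and 0.931 ± 1.03 CPM). Lymphoid priming had 1 of 20 called lower, Il12a (103 ± 47.1 and 292 ± 43.0 CPM), and 2 adjusted over the list alone (median -1.42, camera adjusted p = 1.61e-07; adjusted p = 0.272 with an estimated correlation), with Satb1 at -1.82. Granulocyte-monocyte genes had 0 calls (median -0.30, camera adjusted p = 0.135), with Spi1 at -1.05. T and NK cell markers lay lower in MPP2 (median -1.07, camera adjusted p = 0.0313; adjusted p = 0.465 with an estimated correlation), with 3 of 11 adjusted over the list alone. Within numbers 1 and 2, and within 3 and 4, medians were 1.37 and 4.81 for megakaryocyte-erythroid, 1.07 and 0.65 for cell cycle, 0.31 and 0.61 for oxidative phosphorylation, 0.28 and 0.73 for stem cell identity, -0.48 and -4.74 for lymphoid priming, and 0.57 and -2.32 for granulocyte-monocyte genes. In these, 2 and 322 genes passed. Lower in MPP2 were also Adgrg3 (217 ± 93.6 and 600 ± 112 CPM), Tmem243, Msrb3, Dhrs3, Fbxo32, Sh2d5 and Rgl1 (-2.08, -1.95, -1.73, -1.63, -1.61 and -1.44). The count of 253 genes changed to 164, 458, 97 and 64 without WT MPP2 1, 2, 3 and 4, and to 89, 70, 121 and 41 without WT MPP3 1, 2, 3 and 4. Of the 25 called genes named here, 6 stayed called in all 8 omissions, namely Cavin2, Tek, Slamf1, Apoe, Aqp1 and Nusap1. With the mouse as a block 20 of the 25 stayed called, these 6 among them, and Tmem243, Sh2d5, Adgrg3, Nupr1 and Ube2c no longer passed. Phf6 did not differ between the WT populations beyond the spread of libraries, at log2 fold changes of 0.13, 0.20 and 0.07 (edgeR adjusted p = 0.965, 1 and 0.976).

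**Figure D3:**
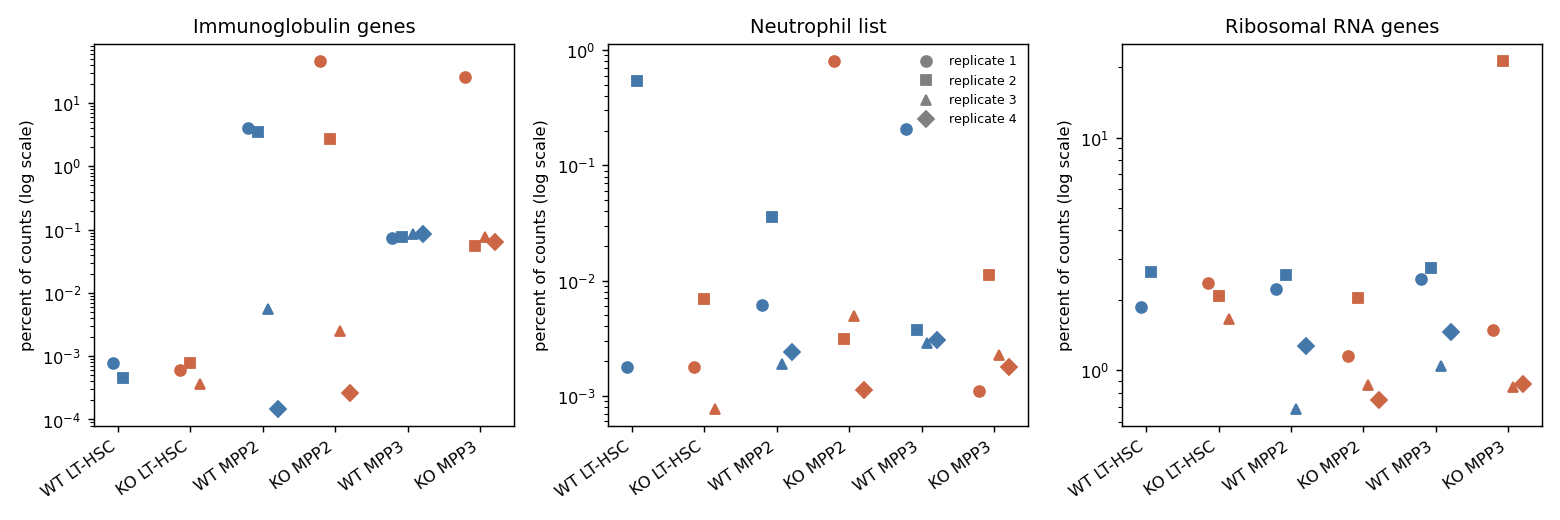
Percent of counts in immunoglobulin genes, neutrophil markers and ribosomal RNA genes, 1 point per library on a log scale. KO MPP2 1 and KO MPP3 1 stand out with 45.8% and 25.8% of counts in immunoglobulin genes, and KO MPP3 2 with 21.2% in ribosomal RNA genes.

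**Figure D4:**
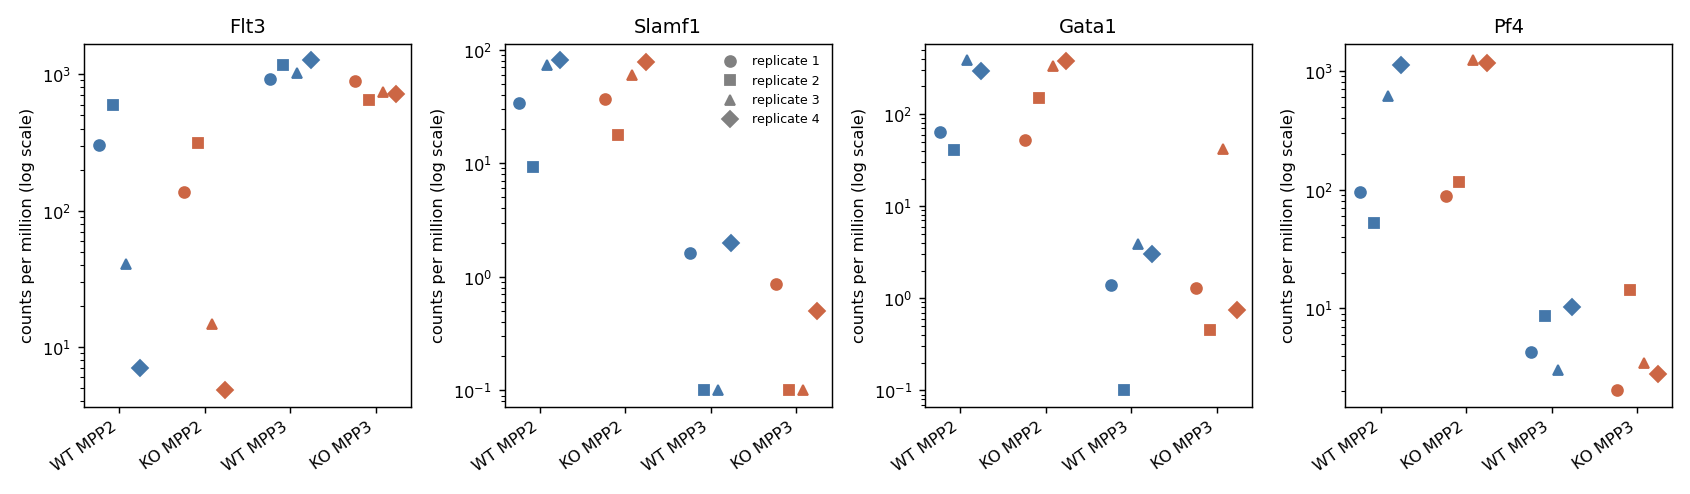
Levels of marker genes in CPM on a log scale in MPP2 and MPP3, 1 point per library, with values under 0.1 drawn at 0.1. In MPP2, Flt3 was at 137 to 591 in the libraries numbered 1 and 2 and at 4.81 to 40.9 in those numbered 3 and 4, in KO and WT alike.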

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

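The tests of list differences between populations, and those of loss of Phf6, of carry-over and of a strain or transgene difference, were chosen after the results were seen. In 126 sets of 4 libraries, 1 library lay far from the other 3 in 23 sets by Dixon's criterion. About 6 would be expected for normally distributed values. Percents and CPM are skewed and the sets share libraries, so the 6 is no firm measure of chance.

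Among the library measures, KO MPP2 1 had 45.8% of counts in immunoglobulin genes (next library 2.67%), 0.798% in neutrophil markers (next 0.00491%) and a TMM factor of 0.496 (next 0.989). KO MPP3 1 had 25.8% in immunoglobulin genes (next 0.0772%) and 23984 genes with at least 1 count (next 21827). KO MPP3 2 had 21.2% in ribosomal RNA genes (next 1.49%) and 0.0112% in neutrophil markers (next 0.00225%). Neutrophil markers took 0.0354% in WT MPP2 2 (next 0.00615%) and 0.207% in WT MPP3 1 (next 0.00375%).

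Among named genes, KO MPP2 1 stood apart in Hdlbp (171 CPM, next 119), the lymphocyte antigen Cd52 (3157, next 286) and the neutrophil granule genes Ngp (3396, next 2.63) and Camp (893, next 1.10). KO MPP2 3 was low in the kinase Tyk2 (22.75 CPM, next 33.8). KO MPP3 3 was low in Eya2 (8.70, next 24.3) and high in Bub1b (113, next 71.1), and KO MPP3 2 was high in Polr1a (83.3, next 34.0). KO MPP3 1 was high in the antibody genes Jchain (12788 CPM, next 2.35) and Igkc (148450, next 2.81). WT MPP2 2 was high in Zfp951 (33.8 CPM, next 21.4), WT MPP3 3 low in Muc13 (175, next 219) and high in Cd200r3 (3.52, next 0.122), and WT MPP3 4 high in Hsph1 (42.1, next 31.1).

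The KO effect on a list differed between populations in 14 of 87 camera tests with the preset correlation, and in 0 with an estimated correlation (adjusted p = 0.995). The granulocyte-monocyte list had a median log2 fold change of -1.13 in LT-HSC, and differed from that in MPP2 (0.02, camera adjusted p = 6.55e-05) and in MPP3 (0.21, 8.84e-08). The histone list differed between LT-HSC (-0.31) and MPP3 (0.68; camera adjusted p = 1.67e-11) and between MPP2 and MPP3 (2.29e-08). Ribosomal proteins differed between LT-HSC and MPP2 (camera adjusted p = 6.36e-05) and between MPP2 and MPP3 (3.55e-12). Oxidative phosphorylation did so too (camera adjusted p = 0.000512 and 0.000155). Neutrophil markers differed in all 3 pairs (camera adjusted p = 1.41e-05 for LT-HSC and MPP2, 0.0299 for LT-HSC and MPP3, 0.00107 for MPP2 and MPP3). Each population had 1 library rich in them, WT LT-HSC 2 (0.535% of counts), KO MPP2 1 (0.798%) and WT MPP3 1 (0.207%). Without it the population's own neutrophil call was lost, and the differences were not tested without these libraries. Stem cell identity differed between LT-HSC and MPP2 (camera adjusted p = 0.01004), and cell cycle (0.000103) and interferon (0.0393) between MPP2 and MPP3.

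Immunoglobulin transcripts filled the MPP2 and MPP3 libraries of KO mouse 1, with Ighv5-4 at 89.0% and 86.2% of heavy chain variable gene counts in them. Loss of Phf6 is argued against in MPP3, where the median share of KO mice 2 to 4 was 0.738 of the highest WT share. In MPP2 this test cannot decide. Its KO median fell on a library numbered 3 or 4, and such MPP2 libraries of both genotypes had at most 0.00561% of counts. Carry-over of reads from the MPP2 into the MPP3 library is argued against, since S100a8 was carried over at 0.00238 of the proportion of immunoglobulin. Antibody-secreting cells or their RNA in the sorted cells may be a source, as 14 of 14 plasma cell markers lay above every WT library in both populations, with Jchain at 44141 and 12788 CPM and Xbp1 at 3367 and 1467 CPM. The lineage cocktail and the gates on Sca-1 and cKit are meant to remove such cells, and a condition of mouse 1 itself was not tested. Such transcripts were not confined to KO mouse 1. Immunoglobulin genes took 4.08%, 3.515% and 2.67% of counts in WT MPP2 1, WT MPP2 2 and KO MPP2 2, with other top heavy chain variable genes. Jchain reached 10024 CPM in WT MPP2, and Fkbp11, also of the 14 markers, 57.6 CPM against 63.4 in KO MPP2 1.

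Sva had at least 14 counts in all 11 KO libraries and at most 1 in the 10 WT libraries, and no other gene had at least 10 counts in every KO library and at most 1 in every WT library. A change of the whole chromosome 6 region is argued against by a median log2 fold change of -0.14 (quartiles -0.55 and 0.12) over the 20 tested genes within 1 Mb. Reads shared with the paralogs Sval1, Sval2, Sval3 and Pip are argued against by a ratio of 106 for the summed family, since a shift of reads within the family would leave its sum alike. Loss of Phf6 and a strain, transgene or passenger difference between KO and WT mice cannot be told apart, because each could give Sva in 11 of 11 KO libraries.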

How the results depend on the processing

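The fits without 3 libraries, without immunoglobulin genes and with a batch term, and the list tests that join the block with an estimated correlation or fry, were chosen after the data were seen. Over 182 results for named genes, 2538 values under the alternatives stayed on their side of the threshold, 342 no longer passed, 34 newly passed, 72 that had not passed moved by more than 1 SE or had no adjusted p, and 0 called ones turned. Causes of these shifts were not tested. No library had so few genes that the planned omission of low-complexity libraries removed one.

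For KO against WT, DESeq2 called 30 genes in LT-HSC (14 higher, 16 lower), 45 in MPP2 (22, 23), 50 in MPP3 (32, 18) and 72 in the sums (26, 46). It called 898 for WT LT-HSC against MPP2, 661 for WT LT-HSC against MPP3 and 966 for WT MPP2 against MPP3, and 25, 27 and 13 for the KO effect between LT-HSC and MPP2, LT-HSC and MPP3, and MPP2 and MPP3. Limma voom called 6 in LT-HSC, 8 in MPP3, 0 in the sums, and 1455, 1663 and 677 between the WT populations. With only the groups compared in the fit, the counts were 0 in LT-HSC, 1 in MPP2, 1 in MPP3, and 46, 791 and 157 between the WT populations. The count for WT LT-HSC against MPP3 thus rose from 232, while the others fell. Without a filter, WT LT-HSC against MPP2 gave 54 and WT MPP2 against MPP3 158. With the replicate block the counts were 9 in MPP2, 8 in MPP3, 0 in the sums and 54 for WT LT-HSC against MPP2, and it changed no other count by over 1.5 times. With KO LT-HSC 3 set to mouse 4 in the block, edgeR called 0 genes for the KO effect between LT-HSC and MPP2 or MPP3 (692 and 496 at an unadjusted p under 0.05). Without the 3 libraries with immunoglobulin or rRNA reads the counts were 0 in MPP3, 0 in the sums and 513, 363 and 646 between the WT populations. The batch term gave 1 in the sums.

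Leaving out each library in turn gave 0 to 0 genes in LT-HSC, 0 to 3 in MPP2, 0 to 2 in MPP3 and 0 to 4 in the sums. It gave 0 to 124 for WT LT-HSC against MPP2, 51 to 147 for WT LT-HSC against MPP3 and 41 to 458 for WT MPP2 against MPP3.

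The log2 fold change of Phf6 in LT-HSC was -3.98 with only the groups compared, -4.28 with the block, -4.25 with the batch term and -4.25 to -3.68 on leaving out 1 library, none past the edgeR threshold. In LT-HSC the block and the batch term both fit KO LT-HSC 3 apart, so they are not separate from leaving that library out. In MPP2 the log2 fold change of Phf6 was -3.42 with the block and -3.79 to -3.27 on leaving out 1 library. In MPP3 it was -3.84 with only the groups compared, -3.36 without the 3 libraries and -4.11 to -3.55 on leaving out 1 library. In the sums it was -3.52 with voom, -3.58 with the block, -3.45 without the 3 libraries, -3.63 with the batch term and -3.94 to -3.42 on leaving out 1 mouse.

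Gene lists called in LT-HSC, MPP2, MPP3 and the sums were 8, 7, 9 and 9 with the preset correlation, and 0, 0, 0 and 0 both with an estimated correlation and by fry. The block gave 10, 7, 8 and 13, and 0 in each when joined with an estimated correlation or fry, and leaving out 1 library 6 to 10, 5 to 10, 6 to 12 and 5 to 14. A gene at 0 counts in a group of 4 libraries could still lie under 3 counts, so depth limits folds such as that of Sva in MPP2 to lower bounds.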

Other observations

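The tests of the MPP2 libraries by number and of the splits were planned before their results were seen, and the choice to look at the numbers 1 and 2 against 3 and 4, and the test of a batch on lists other than lymphoid priming, were made after the data were seen. In WT mice, Hox and Meis genes, regulators of stem cell self-renewal, lay higher in LT-HSC than in MPP2 (median log2 fold change 1.48, camera adjusted p = 1.15e-06; adjusted p = 0.150 with an estimated correlation) and than in MPP3 (median 1.08, camera adjusted p = 1.08e-06; adjusted p = 0.150 with an estimated correlation). Replication-dependent histones, made in S phase, lay lower in LT-HSC than in MPP2 (median -1.30, camera adjusted p = 6.47e-13; adjusted p = 0.150 with an estimated correlation), with 1 of 58 called over all genes and 13 adjusted over the list alone. They lay higher in MPP2 than in MPP3 (median 0.84, camera adjusted p = 8.27e-11; adjusted p = 0.190 with an estimated correlation). Interferon response genes lay lower in MPP2 than in LT-HSC (median 0.55 for LT-HSC against MPP2, camera adjusted p = 0.00257; adjusted p = 0.638 with an estimated correlation) and than in MPP3 (median -0.49, camera adjusted p = 0.000229; adjusted p = 0.534 with an estimated correlation). Markers of later erythroid cells lay higher in MPP2 than in MPP3 (median 1.47, camera adjusted p = 6.97e-06; adjusted p = 0.130 with an estimated correlation), with 1 of 13 called over all genes and 6 adjusted over the list alone. Each of these medians kept its sign with the MPP2 and MPP3 libraries numbered 1 and 2 alone and with those numbered 3 and 4 alone.

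Of the lists compared between KO and WT, 14 passed in none of the 4 comparisons. Over these comparisons the camera adjusted p ran from 0.400 to 0.814 for quiescence, 0.0911 to 0.547 for TNF NF-kB, 0.400 to 0.764 for JAK-STAT, 0.190 to 0.989 for p53 and 0.337 to 0.758 for immediate early and heat shock genes. It ran from 0.724 to 0.971 for glycolysis, 0.292 to 0.724 for Notch, 0.547 to 0.949 for NuRD and PAF1, 0.485 to 0.843 for TGF-beta and adhesion and 0.507 to 0.785 for apoptosis. For T and NK cells the camera adjusted p ran from 0.0979 to 0.453, for erythroid cells from 0.453 to 0.874, for macrophages from 0.400 to 0.989 and for mitochondrially encoded genes from 0.337 to 0.912. In MPP2 the cell cycle and interferon lists did not pass (camera adjusted p = 0.453 and 0.271), nor did stem cell identity in LT-HSC and MPP3 (0.976 and 0.307).

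The 8 libraries of a comparison can be split into 4 and 4 in 35 ways. For KO against WT MPP3, 1 of 35 splits, the real one, gave as many genes (2, highest other 1). For WT MPP2 against WT MPP3 it was likewise 1 (253, highest other 0). These shares are under 0.05 only with the libraries taken as unpaired, whereas the numbers were taken to mark mice and pairs. So they do not exclude chance for these counts, and 1 of the 2 genes in MPP3 was Phf6, the gene knocked out. Even as unpaired, the share was not under 0.05 for KO against WT MPP2, where 4 of 35 splits gave as many (3, highest other 665). Nor was it for the sums, where 2 did (2, highest other 1511), or for the difference of the KO effect between MPP2 and MPP3, where all 35 did (0, highest other 65). In these 3 the highest other split put numbers 1 and 2 against 3 and 4, which points to a structure of the samples. Taken as pairs, the libraries or sums have 8 splits that part all 4 pairs, too few for a share under 0.05. The real split gave 3 genes in MPP2, 2 in MPP3, 2 in the sums and 253 in WT MPP2 against WT MPP3, and the highest of the 7 others 0 in each. The others differ from it in exchanging the 2 members of 1 or 2 pairs. As many gene lists came from 23 of 35 splits in MPP2 (7, highest other 16), 16 in MPP3 (9, highest other 12) and 17 in the sums (9, highest other 17), so chance cannot be excluded for the numbers of lists. Within the 8 splits, 3, 2 and 2 gave as many lists.

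MPP2 libraries numbered 1 and 2 differed from those numbered 3 and 4 in 1331 genes (951 higher in 1 and 2), against 115 in MPP3, with 2 KO and 2 WT libraries on each side. Flt3 was at 137 to 591 CPM against 4.81 to 40.9, Slamf1 at 9.18 to 37.0 against 59.6 to 80.1, Gata1 at 41.3 to 149 against 293 to 383 and Pf4 at 52.1 to 116 against 612 to 1222. Immunoglobulin genes took 2.67% to 45.8% of counts against at most 0.00561%, with both genotypes on each side. A sequencing or library batch that changes levels by the same fold in all libraries is argued against for the lymphoid priming difference. That difference in MPP3 (median 0.14, quartiles -0.21 and 1.04) was 0.0403 of that in MPP2 (3.50, quartiles 2.16 and 5.56). The test cannot decide on a batch that adds the same amount of lymphoid RNA to each library. MPP3 libraries already had Flt3 at 645 to 1262 CPM, so such an amount would give a smaller fold there. A batch of the same fold is argued against for the granulocyte-monocyte difference too, with medians of 2.26 in MPP2 (quartiles 0.60 and 4.40) and -0.98 in MPP3 (quartiles -1.89 and -0.39), a ratio of -0.431. For the megakaryocyte-erythroid difference the ratio was 0.0825 (-1.54 and -0.13), but the quartiles overlapped (-2.02 and -0.78 in MPP2, -1.15 and 0.50 in MPP3), so it stays open there. It also stays open for 3 lists that moved alike. In MPP2 and MPP3 the medians were 1.02 and 0.70 for mitochondrially encoded genes, -0.47 and -0.42 for ribosome biogenesis and 3.65 and 3.01 for neutrophil markers, with a lowest MPP3 to MPP2 ratio of 0.690. Over 29 lists, 13 had an MPP3 median of the same sign and at least 50% of that in MPP2, and 6 one of the other sign. Ribosomal RNA took 1.15% to 2.76% of counts in the MPP2 and MPP3 libraries numbered 1 and 2, KO MPP3 2 (21.2%) aside, and 0.684% to 1.47% in those numbered 3 and 4. For the 3 lists and this share a batch and a difference between the mice cannot be told apart, since no mouse has libraries in both. Flt3-expressing cells of lower CD150 in the MPP2 sort of mice 1 and 2 are a candidate explanation, with the megakaryocyte-erythroid list at a median of -1.54 and no Flt3 stain in the sort. A biological difference between the mice stays open for every part of this pattern and was not tested.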
